A study of Pomacea canaliculata with 36 samples.

How the data were processed

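The series holds RNA sequencing of polyadenylated RNA from eye stalks of *Pomacea canaliculata*, extracted with Trizol per the labels' protocols, in 36 libraries. The group of each library (Intact, 1dpa, 3dpa, 6dpa, 9dpa, 12dpa, 15dpa, 21dpa or 28dpa, where dpa is days post amputation) and its replicate number, 1 to 4, were taken from its label. The submitters' design text lists a day 7 group in place of day 6 (7 against 6 in its labels), and the label of each library was followed. The authors deposited 1 table of raw read counts per gene for all libraries. The submitters' processing notes name STAR as the aligner, and its version, the genome build, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes that overlap, or that have near-identical copies, can therefore share counts in ways that cannot be separated here.

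All 21131 rows carry locus identifiers, and all of them matched the symbol of a protein-coding gene in a RefSeq gene table of the assembly ASM307304v1. That table gives no product names. The 13 protein-coding genes of it that have no row in the count table are all mitochondrial and are not analysed here. The gene lists, the comparisons, the rule for named genes and the first set of alternatives given below were fixed before the data were examined. The 25 gene lists, among them lists for phototransduction, lens, eye development, neurons, the cell cycle, immunity and the extracellular matrix, select members by product name, found 0 members each, and could not be tested. Genes were therefore named by the rule fixed for that case, at most 2 that rose and 2 that fell per comparison, taking the largest log2 fold changes among genes with an adjusted p below 0.05, a mean of at least 5 CPM in the higher group and no overlap between the 4 and 4 libraries. The 3 most abundant genes, and the runs of neighbouring genes in the closing section, were chosen after their values had been seen. The gene table was also used for which of the tested genes neighbour each other.

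Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of the 21131 genes, 615 had no count. The filterByExpr rule on the 9 groups left 17341 genes, which held at least 99.98% of the counts of each library. Counts were scaled by TMM factors, and 1 quasi-likelihood model (glmQLFit, robust, a mean per group, no other term) was fitted to all 36 libraries, so that the groups share the estimate of the spread. Each time point was tested against Intact, neighbouring time points were tested against each other, and 28dpa against 1dpa, 16 comparisons in all, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An F test covered all 9 groups. The text gives CPM from TMM-scaled library sizes as mean ± SD over 4 libraries, and log2 fold changes with the standard error from the F statistic. Against a group with no count a fold is a lower bound, taking 3 counts over the group; no fold is given for a gene with 1 to 3 counts in the lower group. These bounds cover counting error only. Distances between libraries were Euclidean, on log2 CPM of the 500 genes of largest variance, with permutation tests over all splits of the computed distances. For the change left at later times, genes were chosen on replicates 1 and 2 and measured on replicates 3 and 4 as the log2 ratio of summed counts.

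The 54 pairs of libraries within groups were compared by a chi-square test of their counts; the lowest statistic per degree of freedom was 9.78, so no pair agreed within sampling noise. At 19.3 counts per CPM in the smallest library, genes of few CPM are measured with a counting error of their own. The tests were tried on simulated data with known changes. For 1dpa against Intact, in 16845 genes with 200 changed, 77% of the genes changed 2-fold and 95% of those changed 4-fold were recovered, with 7 false calls, and 0 genes were called in the simulated, unchanged pair of 28dpa and 21dpa. For 12dpa against the mean of 9dpa and 15dpa, 97% of 200 genes changed 4-fold were recovered in 16840 genes, with 7 false calls. Both simulations changed few genes, as many up as down, whereas in the data 76.9% of the tested genes were called at 1dpa. They therefore do not show recovery or false calls where most genes change.

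The first set of alternatives held DESeq2's size factors (RLE) or library size alone as scaling, no filter or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample weights, a fit to only the groups compared, a term for the replicate number, a log2 fold change of at least 1, and each library left out in turn. After the data had been seen, fits without the 12dpa libraries, with every library thinned to the smallest total and without the 10 genes of most counts were added, as was the contrast of each middle time point with its neighbours weighted by day. Other splits of the libraries were counted for each comparison, all 35 for each pair of groups, and 100 drawn for the F test and for 9dpa, 12dpa and 15dpa. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.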

Results

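Polyadenylated RNA was measured by RNA sequencing in eye stalks of *Pomacea canaliculata*, the apple snail, a freshwater gastropod whose eye sits at the tip of a stalk. The series followed the regeneration of the eye after amputation. The 36 libraries fell into 9 groups of 4: Intact, and 1, 3, 6, 9, 12, 15, 21 and 28 days post amputation (dpa). Total counts per library lay between 21797015 and 32928737, and 1 CPM, on library totals scaled by TMM factors, stood for 19.3 counts in the smallest library. The 12dpa libraries were the deepest, at 31.4 ± 2.19 M counts (SD, n = 4), and the Intact libraries held 24.5 ± 1.52 M. Between 17936 and 18798 of the 21131 genes had a count in each library, and 17341 genes were tested. Genes carry only their locus identifiers here, because the sources used here do not pair them with product names, so the text describes groups of genes by how they moved and names at most 2 that rose and 2 that fell per comparison, apart from the most abundant genes. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

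The first comparison asked what amputation had changed in the stalk by 1dpa. Amputation removes tissue, so a fall from Intact may come from cells no longer there, and a rise from the larger share of those left. These cannot be told apart here from changes within cells. Some genes without a count in the intact stalk appeared, and some seen in it were nearly lost. LOC112557630 had no count in the 4 Intact libraries and stood at 11.6 ± 6.03 CPM (SD, n = 4) at 1dpa, at least 406.5-fold higher, taking 3 counts over the Intact group as the floor. LOC112558610, also without a count in Intact, reached 5.52 ± 1.23 CPM, at least 186.9-fold higher. In the other direction LOC112577424 fell from 14.4 ± 5.32 CPM to no count, at least 445.2-fold lower, and LOC112569172 fell from 10.7 ± 0.666 CPM to a single count in the 4 libraries. In all, 6451 genes were higher and 6879 lower at 1dpa than in Intact (edgeR quasi-likelihood test, adjusted p below 0.05), 76.9% of the genes tested. Scaled by library size alone, 40.2% of the calls at 1dpa were upward in place of 48.4%. The strong changes leaned downwards. Of the called genes 4726 were lower by 2-fold or more against 3176 higher, and 1290 were lower by 8-fold or more against 680 higher.

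**Figure D1:**
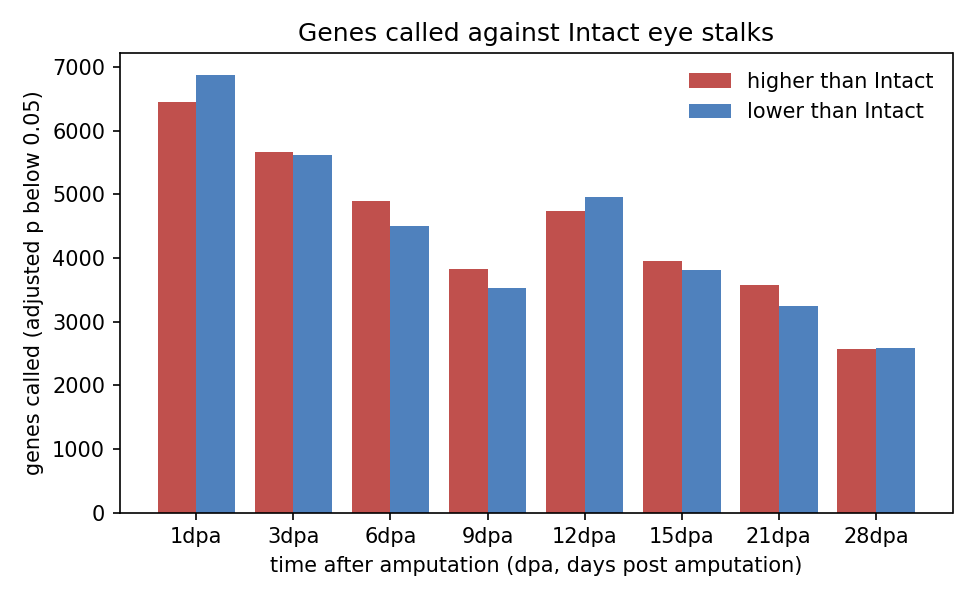
Bars give the number of genes called higher (red) or lower (blue) than in the Intact stalks at each time point (edgeR quasi-likelihood test, adjusted p below 0.05, 17341 genes tested, n = 4 libraries per group). The total went from 13330 at 1dpa to 5169 at 28dpa, and was larger at 12dpa (9714) than at 9dpa (7361) or 15dpa (7770).

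At 3dpa and 6dpa LOC112577424 and LOC112569172 were still nearly absent, and further genes had come up. LOC112568715, at 0.295 ± 0.127 CPM in Intact and 0.742 ± 0.297 CPM at 1dpa, stood at 24.8 ± 6.20 CPM at 3dpa and 53.7 ± 7.86 CPM at 6dpa (n = 4 each). Its log2 fold change against Intact was 6.39 ± 0.749 (SE; adjusted p = 1.12e-08, edgeR) at 3dpa and 7.50 ± 0.732 at 6dpa. LOC112563688 was at 8.77 ± 2.65 CPM at 6dpa against 0.0382 ± 0.0324 CPM in Intact. LOC112561488 was already up at 1dpa, with 0.0897 ± 0.0429 CPM in Intact, 11.5 ± 2.25 CPM at 1dpa, 8.09 ± 3.62 CPM at 3dpa and 1.07 ± 0.633 CPM at 6dpa. LOC112577424 had no count at either time and LOC112569172 was below 0.1 CPM on average, and LOC112562505, at 6.53 ± 2.13 CPM in Intact, had none at 3dpa, at least 239.2-fold lower. LOC112576458, a gene of 8666 ± 2070 CPM in the intact stalk, was at 1.29 ± 0.796 CPM at 6dpa, a log2 fold change of -12.69 ± 1.41 (adjusted p = 6.76e-09, edgeR). At 3dpa 5672 genes were higher and 5619 lower than in Intact, and at 6dpa 4891 were higher and 4503 lower. Changes of 8-fold or more were downward in 829 genes and upward in 251 at 3dpa, and downward in 556 and upward in 106 at 6dpa.

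At 9dpa 3832 genes were higher and 3529 lower than in Intact, with 284 lower and 60 higher by 8-fold or more. LOC112568715 remained high, at 25.5 ± 20.8 CPM, and LOC112561517 reached 9.72 ± 13.3 CPM from 0.147 ± 0.122 CPM, with an SD above its mean. LOC112566244 was at 0.0740 ± 0.0533 CPM against 18.1 ± 7.43 CPM in Intact. LOC112571947, at 3673 ± 476 CPM in Intact, was at 19.5 ± 9.44 CPM, a log2 fold change of -7.56 ± 0.719 (adjusted p = 4.32e-10, edgeR).

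At 12dpa more genes were called against Intact than at the time points on either side of it, but not more with changes of 8-fold or more than at 9dpa. There 4747 genes were higher and 4967 lower, and 2094 were lower and 1556 higher by 2-fold or more, 196 lower and 122 higher by 8-fold or more. Scaled by library size alone, 41.1% of the calls at 12dpa were upward in place of 48.9%. LOC112575956, with 1 count in the 4 Intact libraries, stood at 7.46 ± 4.29 CPM, and LOC112564790 at 5.72 ± 9.50 CPM against 2 counts in Intact. The mean of LOC112564790 came largely from 12dpa replicate 2, at 19.9 CPM, with the others between 0.323 and 1.90 CPM. Without that library the gene was still called by edgeR. LOC112563154 was at 0.152 ± 0.0861 CPM against 35.5 ± 40 CPM, and LOC112562198 at 0.170 ± 0.0744 CPM against 16.1 ± 6.35 CPM. At 15dpa the counts were 3953 higher and 3817 lower, with 146 lower and 108 higher by 8-fold or more. LOC112575956 was at 10.5 ± 4.12 CPM, and LOC112567961, without a count in Intact, reached 7.64 ± 5.21 CPM, at least 260.8-fold higher. LOC112562198 and LOC112567275 were the named falls at 15dpa, the second at 0.0281 ± 0.0563 CPM against 7.44 ± 9.34 CPM in Intact. At 21dpa 3579 genes were higher and 3244 lower, with 84 lower and 69 higher by 8-fold or more. LOC112575956 and LOC112568715 were still up, at 6.03 ± 0.345 and 10.5 ± 6.19 CPM, and LOC112562198 and LOC112576458 still down, at 0.270 ± 0.133 and 216.2 ± 23.2 CPM. With library size alone as the scaling, 34.5% of the calls at 21dpa were upward in place of 52.5%.

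By 28dpa, the last time point, 2578 genes were still higher and 2591 still lower than in Intact, 29.8% of the genes tested. Strong differences were few, with 63 genes higher and 41 lower by 8-fold or more. LOC112562198 was at 0.161 ± 0.0588 CPM against 16.1 ± 6.35 CPM in Intact, a log2 fold change of -6.61 ± 0.303 (adjusted p = 5.83e-21, edgeR), and lay below 1 CPM on average at every time point after amputation. LOC112560581 was at 12.0 ± 1.21 CPM against 351.7 ± 58.2 CPM, a log2 fold change of -4.87 ± 0.298 (adjusted p = 8.66e-14, edgeR). The named rises, LOC112560725 at 11.8 ± 19.8 CPM and LOC112566787 at 26.2 ± 43.8 CPM, each rested largely on 1 library. Without 28dpa replicate 1 the log2 fold change of LOC112560725 was 3.73 in place of 6.38, and it was no longer called (adjusted p = 0.131, edgeR). Its counts in Intact all came from replicate 2, and without that library the fitted value was 11.28 (adjusted p = 0.0108, edgeR), which depends on the prior count, as no count is left in Intact. Without 28dpa replicate 2 the log2 fold change of LOC112566787 was 2.31 in place of 4.89 (adjusted p = 0.000273, edgeR). With library size alone as the scaling, 27.6% of the calls at 28dpa were upward in place of 49.9%.

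**Figure D2:**
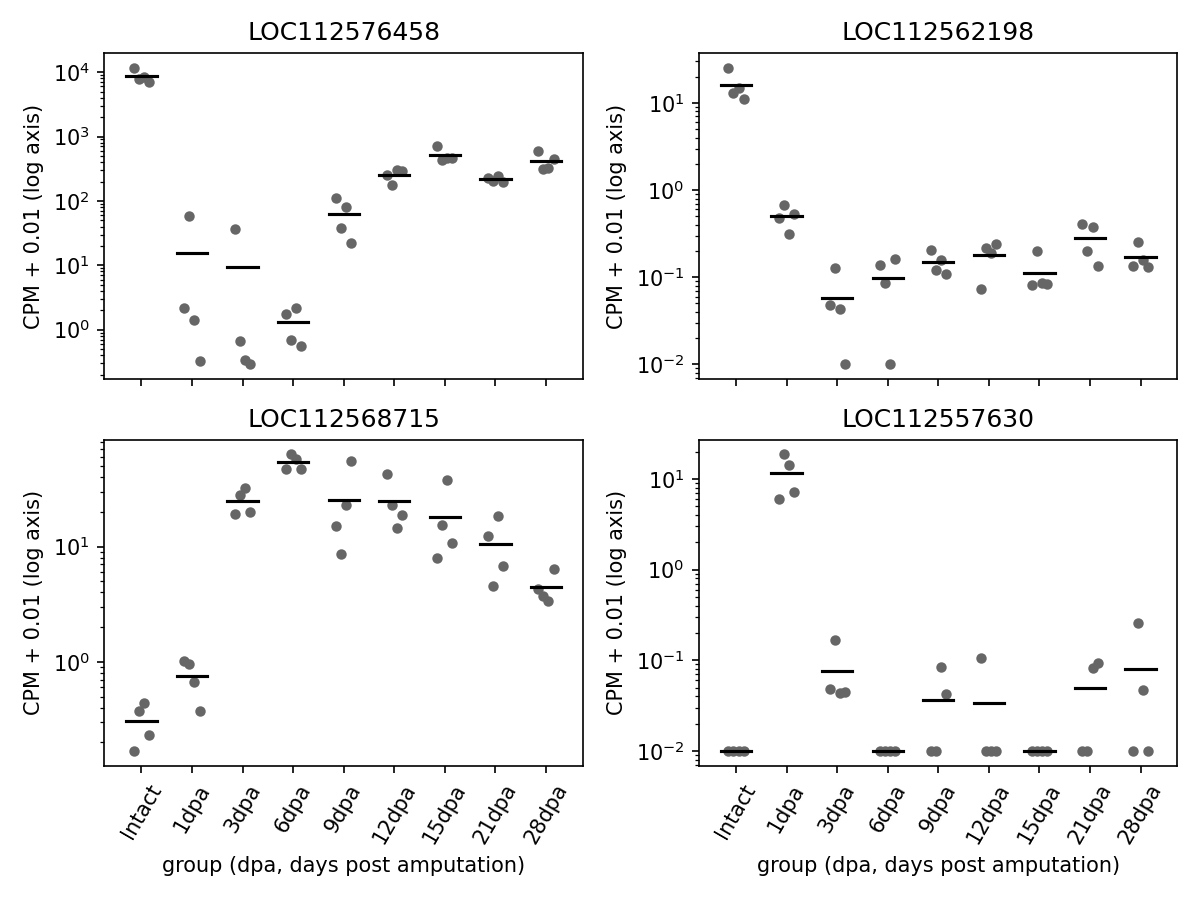
CPM per library with 0.01 added, on a log axis, in each group for 4 genes (points, n = 4 libraries per group; horizontal lines, group means). LOC112576458 fell from 8666 CPM in Intact to 1.29 at 6dpa and stood at 417.3 at 28dpa, LOC112562198 stayed below 1 CPM on average after amputation, LOC112568715 was highest at 6dpa (53.7 CPM), and LOC112557630 was at 11.6 CPM at 1dpa and below 0.1 CPM on average in every other group.

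Of the 3 genes with the most counts in the series, LOC112556452 and LOC112556451 took similar courses and LOC112562530 took another. All 3 were chosen for their abundance after the values had been seen. Reads that fit both LOC112556452 and LOC112556451 cannot be separated here, so how far their courses are independent is not known. LOC112556452 and LOC112556451 were together 4.56 ± 1.15% of all counts in Intact libraries (SD, n = 4), 2.42 ± 0.962% at 1dpa, and 15.3 ± 2.42% at 28dpa. LOC112556452 went from 23640 ± 5810 CPM in Intact to 80460 ± 18800 CPM at 28dpa, a log2 fold change of 1.77 ± 0.224 (adjusted p = 3.02e-07, edgeR), and LOC112556451 from 19930 ± 5250 to 82390 ± 16200 CPM, 2.05 ± 0.219 (adjusted p = 1.31e-08). LOC112562530, at 29000 ± 4450 CPM in Intact, fell to a mean of 94.0 CPM at 1dpa (17.1 to 231.9 in the single libraries, n = 4), a log2 fold change of -8.27 ± 0.811 (adjusted p = 1.91e-10, edgeR). Of the 1dpa libraries replicate 2 held the most of it, as it did of LOC112576458, at 58.2 CPM against 0.311 to 2.14 CPM in the others, and so did 3dpa replicate 1, with LOC112576458 at 36.8 CPM against 0.278 to 0.667 CPM. LOC112562530 stood at 2815 ± 1440 CPM at 9dpa and 15170 ± 5850 CPM at 12dpa. At 28dpa it was at 22380 ± 3940 CPM and was not called against Intact (log2 fold change -0.37 ± 0.590, adjusted p = 0.673, edgeR).

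Neighbouring time points were compared to ask when genes moved. Between 1dpa and 3dpa 5014 genes rose and 4616 fell. LOC112571941 rose from 10.3 ± 1.27 to 248.1 ± 30.0 CPM, and LOC112568715 also rose. LOC112557630 and LOC112564713, the latter at 11.3 ± 5.98 CPM at 1dpa, fell to 0.0658 ± 0.0608 and 0.0632 ± 0.0333 CPM. Between 3dpa and 6dpa 2642 genes rose and 2788 fell, and of the changes of 2-fold or more 1236 were rises and 453 falls. LOC112570692 rose from 0.574 ± 0.493 to 15.2 ± 3.61 CPM and LOC112568515 from 1.24 ± 0.715 to 28.9 ± 7.12 CPM. LOC112568020 fell from 60.6 ± 39.1 to 5.81 ± 1.78 CPM, and LOC112576040 was at 5.37 ± 7.23 and 0.311 ± 0.216 CPM, a call that was lost without 3dpa replicate 4 (adjusted p = 0.203, edgeR). Between 6dpa and 9dpa 1678 genes rose and 1680 fell, with 722 rises and 115 falls of 2-fold or more. The largest named rises were in genes abundant in the intact stalk. LOC112576458 rose to 63.1 ± 40.6 CPM and LOC112559381 from 3.15 ± 2.25 to 91.0 ± 53.7 CPM, against 4744 ± 751 CPM in Intact. LOC112563688 and LOC112573981 fell from 8.77 ± 2.65 and 5.20 ± 1.13 CPM to 1.85 ± 0.532 and 1.24 ± 0.428 CPM. The 3358 calls between 6dpa and 9dpa became 2162 without 9dpa replicate 3, and 5291 with limma-voom.

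Between 9dpa and 12dpa 2855 genes rose and 2216 fell, but of the changes of 2-fold or more 442 were rises and 774 falls. LOC112567738, at 2479 ± 92.5 CPM in Intact, rose from 19.3 ± 8.24 to 588.8 ± 142.0 CPM, a log2 fold change of 4.93 ± 0.547 (adjusted p = 1.05e-07, edgeR), and LOC112557200 rose from 0.584 ± 0.303 to 8.44 ± 1.71 CPM. LOC112572474 fell from 74.6 ± 8.89 to 4.21 ± 3.32 CPM and LOC112554596 from 7.82 ± 3.34 to 0.612 ± 0.429 CPM. Between 12dpa and 15dpa 2177 genes rose and 2726 fell, with 875 rises and 183 falls of 2-fold or more. LOC112563869, whose counts at 12dpa all came from replicate 1, rose from 3.46 ± 6.92 to 111.6 ± 55.7 CPM and LOC112563154 from 0.152 ± 0.0861 to 7.41 ± 6.56 CPM. LOC112554346 fell from 33.6 ± 35.2 to 0.146 ± 0.106 CPM and LOC112567263 from 38.3 ± 24.7 to 0.212 ± 0.252 CPM. Between 15dpa and 21dpa 1144 genes rose and 1119 fell. LOC112554533 rose from 1.02 ± 0.455 to 10.2 ± 5.05 CPM and LOC112557863 from 1.47 ± 0.268 to 12.7 ± 7.30 CPM, while LOC112574311 and LOC112568029 fell from 6.31 ± 4.66 and 19.9 ± 12.0 CPM to 0.381 ± 0.214 and 1.78 ± 1.29 CPM. The call of LOC112574311 was lost without 15dpa replicate 2 (adjusted p = 0.0588, edgeR), and that of LOC112568029 without 15dpa replicate 2 or 21dpa replicate 1, 2 or 4 (adjusted p from 0.0682 to 0.0988). The 2263 calls of this pair became 1118 without 15dpa replicate 2, 1479 without 15dpa replicate 4, 1213 without 21dpa replicate 2, 1279 when the fit held only these groups, and 3839 with limma-voom.

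The last pair, 21dpa and 28dpa, differed in 159 genes, of which 91 rose and 68 fell. LOC112564308 rose from 19.6 ± 6.79 to 84.7 ± 50.7 CPM and LOC112561620 from 8.51 ± 4.39 to 30.0 ± 11.4 CPM, while LOC112557253 and LOC112564624 fell from 35.7 ± 12.0 and 60.8 ± 18.3 CPM to 11.1 ± 1.73 and 26.6 ± 3.22 CPM. LOC112564308 lost its call without 21dpa replicate 1, 3 or 4 or 28dpa replicate 1 or 4 (adjusted p from 0.0525 to 0.0778, edgeR), and LOC112561620 without 21dpa replicate 4 (adjusted p = 0.0537). The count of 159 depended on the fit. It was 0 when only the 8 libraries of the pair were fitted, 347 with DESeq2 and 316 with limma-voom, and an unadjusted p below 0.05 was seen in 2050 genes in the fit to all libraries. Leaving out a library gave 67 without 21dpa replicate 3, 21 without 21dpa replicate 4, 249 without 28dpa replicate 1, 69 without 28dpa replicate 3 and 47 without 28dpa replicate 4.

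With another scaling the balance of rises and falls between neighbouring time points moved. Under library size alone the share of calls that were rises was 63.9% between 1dpa and 3dpa in place of 52.1%, 66.4% between 3dpa and 6dpa in place of 48.7%, 38.7% between 9dpa and 12dpa in place of 56.3%, 60.8% between 12dpa and 15dpa in place of 44.4%, and 21.8% between 15dpa and 21dpa in place of 50.6%. The median log2 fold change of all genes moved with it from -0.05 to -0.24 at 1dpa, from -0.02 to -0.11 at 12dpa and from 0.02 to -0.12 at 28dpa against Intact, from 0.05 to 0.19 between 1dpa and 3dpa, and from 0.07 to 0.12 between 1dpa and 28dpa.

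Set against each other, the ends of the course, 1dpa and 28dpa, differed in 13069 genes, 75.4% of those tested. Between them 6859 genes rose and 6210 fell, and 1115 rose and 472 fell by 8-fold or more. LOC112577424 rose from no count to 5.74 ± 2.59 CPM, at least 173.7-fold, and LOC112569172 from 1 count in 4 libraries to 7.38 ± 1.49 CPM, both genes that were nearly lost at 1dpa. LOC112566653 fell from 8.10 ± 2.30 CPM to no count, at least 275.6-fold, and LOC112575958 from 9.34 ± 1.26 CPM to 1 count in 4 libraries. Over all 9 groups, 16102 of 17341 genes (92.9%) differed in at least 1 group by the quasi-likelihood F test at an adjusted p below 0.05.

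The distance of each library to the Intact libraries was taken over the 500 genes of largest variance in log2 CPM. Intact libraries lay 30.2 ± 2.70 from each other (SD, n = 4). The distance was 122.2 ± 6.56 at 1dpa, 107.1 ± 4.42 at 3dpa, 95.6 ± 1.24 at 6dpa, 74.0 ± 4.08 at 9dpa, 61.2 ± 5.27 at 12dpa, 59.9 ± 2.64 at 15dpa, 54.0 ± 4.54 at 21dpa and 48.5 ± 6.42 at 28dpa. Each time point differed from Intact, and 28dpa, at 39.7% of the distance of 1dpa, differed from 1dpa (two-sided permutation test over all splits of 4 against 4 libraries, p = 0.0286 for each of 9 tests, the smallest this design allows, and 0.0286 after Benjamini-Hochberg adjustment). Distances were not recomputed for each split, and those of Intact libraries were taken among themselves. The p-values against Intact are therefore approximate. Over all tested genes 12dpa, at 142.1 ± 4.75, was farther from Intact than 9dpa, at 135.8 ± 2.81, the opposite order to that over 500 genes. On the first principal component of all tested genes, with 48.0% of the variance, Intact libraries stood at -81.8 ± 3.83, 1dpa at 148.7 ± 11.2 and 28dpa at -58.4 ± 12.5. On the fourth, with 5.39%, the 12dpa libraries stood apart at -56.2 ± 6.24, with the other group means between -11.0 and 23.2.

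**Figure D3:**
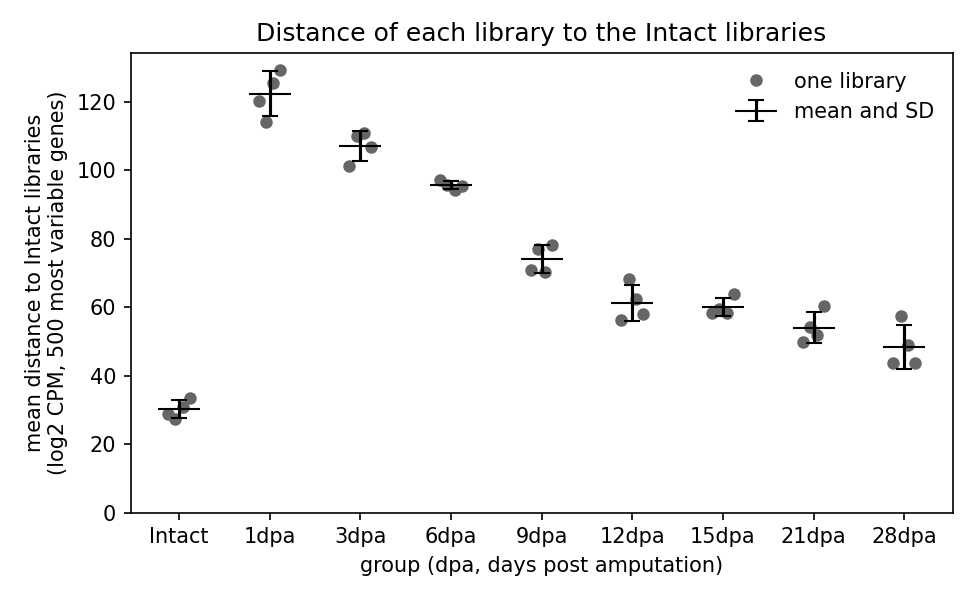
Mean Euclidean distance of each library (points) to the Intact libraries over the 500 genes of largest variance in log2 CPM, with the group mean and SD (n = 4). The group means fell from 122.2 at 1dpa to 48.5 at 28dpa, and Intact libraries lay 30.2 from each other.

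How much of the change at 1dpa was left later was measured on libraries other than those that chose the genes. On replicates 1 and 2, 5513 genes were lower and 5046 higher at 1dpa than in Intact. On replicates 3 and 4 the median log2 fold change of the lower genes was -1.80 at 1dpa, -0.95 at 3dpa, -0.47 at 6dpa, -0.35 at 9dpa, -0.54 at 12dpa, -0.33 at 15dpa, -0.28 at 21dpa and -0.17 at 28dpa. The higher genes mirrored this course, with medians of 1.15, 0.64, 0.43, 0.36, 0.51, 0.32, 0.29 and 0.14 at the same times. In both sets the 12dpa median lay farther from 0 than those of 9dpa and 15dpa. The medians of the 2 single libraries at 12dpa did not overlap with those at 9dpa or 15dpa, which 2 libraries against 2 can give by chance. The 1337 genes that were lower by 8-fold or more at 1dpa were at a median of 8.16% of their Intact level at 1dpa, 14.2% at 3dpa, 25% at 6dpa, 39.9% at 9dpa, 43% at 12dpa, 49.0% at 15dpa, 56.8% at 21dpa and 68.6% at 28dpa. At 28dpa 905 of them were at 50% of Intact or more. Another 38 were still at least 8-fold lower. The 627 genes higher by 8-fold or more at 1dpa fell steeply at first, from a median of 2009% of Intact at 1dpa to 428.4% at 3dpa and 229.0% at 6dpa, then 205.9% at 9dpa, 191.7% at 12dpa, 182.7% at 15dpa, 205.6% at 21dpa and 157.0% at 28dpa. With genes chosen on replicates 3 and 4 and measured on replicates 1 and 2 the late course was another, at 148.2% at 21dpa and 190.2% at 28dpa. No test was made of these medians, and a sum under 3 counts over both libraries was set to 3.

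**Figure D4:**
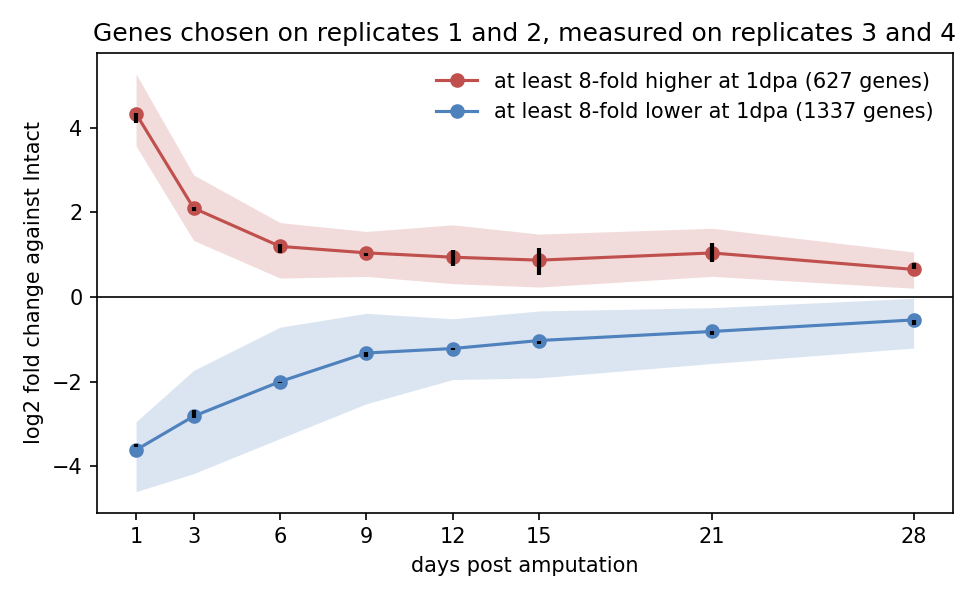
Median log2 fold change against Intact (points and lines) and quartiles (shading) over days post amputation, for the 1337 genes at least 8-fold lower and the 627 genes at least 8-fold higher at 1dpa. Genes were chosen on replicates 1 and 2 and measured on replicates 3 and 4 together; black bars span the medians of the 2 single libraries, which need not enclose that of both together. The lower set went from -3.62 at 1dpa to -0.54 at 28dpa and the higher set from 4.33 to 0.65.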

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

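The tests of the 12dpa course and of its explanations, and the counts of other splits for it, were chosen only after that course had been seen; the search for single libraries far from the rest of their group was planned.

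At 12dpa many genes stood off the straight line between 9dpa and 15dpa. Against the mean of those 2 groups 3350 genes were higher and 2530 lower at 12dpa, 5880 in all (edgeR, adjusted p below 0.05). With library size alone as the scaling the balance turned, to 2199 higher and 3309 lower, 39.9% higher in place of 57%. Departures of 2-fold or more were mostly downward, in 763 genes against 314 upward. For 15dpa against its own neighbours, weighted by day, 2528 genes were called, 3496 for 9dpa, 2324 for 6dpa and 69 for 21dpa, while 3dpa, next to the large first changes, gave 6399. As 12dpa is itself a neighbour of 9dpa and of 15dpa, its departure also adds to their counts. Of the 3350 higher genes 2166 were also higher at 1dpa than in Intact, where 1246 would be shared by independent lists, and 779 were lower there. Of the 2530 lower genes 1638 were also lower at 1dpa, where independent lists would share 1004, and 402 were higher. These comparisons have no library in common. Over all genes higher at 1dpa the mean log2 departure from the midpoint was 0.171 and 0.145 in 12dpa replicates 2 and 3, but 0.0318 and 0.0392 in replicates 1 and 4, within the range of the 9dpa and 15dpa libraries (-0.123 to 0.0669), so on this measure the upward part stood out in 2 of the 4 libraries. Over all genes lower at 1dpa it was -0.210 to -0.133 in the 4 libraries of 12dpa, below the -0.0992 to 0.0911 of the others. Not all genes lost at 1dpa took this course on replicates 3 and 4. An exception was the 498 that were lower by 8-fold or more at both 1dpa and 6dpa on replicates 1 and 2. On replicates 3 and 4 they stood closer to Intact at 12dpa, at a median of 27.8% of it, than at 9dpa (12.7%) or 15dpa (23.1%). The single libraries did not overlap, but 2 libraries against 2 can easily part so by chance.

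The greater depth at 12dpa could not account for this, since 5620 genes were called after every library had been thinned to the smallest total, nor could the most abundant genes, since 5828 were called without the 10 genes of most counts. RNA of 1dpa stalks mixed into the 12dpa libraries is argued against by 28 genes of at least 10 CPM at 1dpa. Their mean over 9dpa and 15dpa was at most 2% of the 1dpa level, and their level in the remaining groups was not asked about. These genes imply a median share of 0.171% (quartiles -0.128 to 0.639), where the 2166 genes higher in both would need a median of 43%. A candidate explanation, left open, is that part of the 1dpa change, though not that of the 498 genes above, recurred at 12dpa: 76.3% of the 4985 genes called in both comparisons moved the same way (77.3% with library size alone), where independent lists would give 49.8% (52%), but this restates the overlap that prompted the explanation and is no separate test of it, and over all genes the correlation was weak (Pearson r = 0.102 across genes, which are not independent replicates). Of 100 splits of these 12 libraries 1, the real one, gave as many genes (5643 called in the fit to these libraries alone, 853 at most in the others). The contrast was chosen after its values had been seen, and the other splits mix groups that differ. The splits therefore cannot say how often chance would give such a course at some time point. The labels give no batch, and one that held the 12dpa libraries alone cannot be told apart from the time point.

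Single libraries lay far from the other 3 of their group in 1 of 36 groups of library measures and in 12 of 92 groups of named-gene values. The cutoff gives about 1 in 20 by chance for normally distributed values. CPM of genes named for large changes need not be so distributed, so no excess over chance is read from this. Groups with fewer than 10 counts were not looked at. The total count of 9dpa replicate 4 was 28.1 M, against 25.1 to 25.5 M in the others. Among genes named as higher, LOC112564790 was at 19.9 CPM in 12dpa replicate 2 (0.323 to 1.90 in the others), LOC112560725 at 41.5 CPM in 28dpa replicate 1 (1.40 to 2.71) and at 0.515 CPM in Intact replicate 2 (0 in the others), and LOC112566787 at 91.9 CPM in 28dpa replicate 2 (2.94 to 6.69). LOC112561620 was at 15.1 CPM in 21dpa replicate 2 (6.19 to 6.40), and LOC112563869 at 13.8 CPM in 12dpa replicate 1 (0 in the others). Among genes named as lower, LOC112576040 was at 16.2 CPM in 3dpa replicate 4 (0.863 to 2.47), and LOC112554596 at 1.25 CPM in 12dpa replicate 3 (0.366 to 0.415) and at 12.8 CPM in 9dpa replicate 3 (5.76 to 6.41). LOC112562198 was at 0.189 CPM in 15dpa replicate 2 (0.0714 to 0.0750), LOC112567263 at 0.585 CPM in 15dpa replicate 4 (0.0357 to 0.113), and LOC112557253 at 13.7 CPM in 28dpa replicate 4 (10 to 10.5).

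Outside the groups searched, several genes abundant in Intact and nearly lost at 1dpa were higher in 1dpa replicate 2 and 3dpa replicate 1 than in the other libraries of those groups, which was seen only on reading their values. LOC112576458 was at 58.2 CPM in 1dpa replicate 2 (0.311 to 2.14 in the others) and at 36.8 CPM in 3dpa replicate 1 (0.278 to 0.667). LOC112571947 was at 24.2 CPM (1.19 to 3.57) and 20 CPM (1.77 to 1.99) in the same libraries, and LOC112559381 at 35.0 CPM (0.415 to 6.56) and 20.2 CPM (0.313 to 1.41). LOC112567738, LOC112560581 and LOC112562530 were also highest in these libraries of their groups. With any 1 library of the groups compared left out, calls against Intact lay between 13036 and 13128 at 1dpa and between 10760 and 11137 at 3dpa. These totals do not show how far the 2 libraries shift the fold changes of the genes above. No explanation of the higher levels in these libraries was tested.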

How the results depend on the processing

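The fits without the 12dpa libraries, with thinned libraries and without the 10 most abundant genes, and every alternative for the 12dpa course, were chosen after the results had been seen; the others were planned. No fold change of a named gene, in the fits where it was taken, and no median of the change left at later times changed sign. But the balance of higher and lower calls changed side with the scaling, under library size alone as given in the report and above. Under RLE it did so for example between 1dpa and 3dpa (46.3% rises in place of 52.1%). Of 200 counts of genes under an alternative, 178 stayed within 1.5 times the main count, as did 135 of 144 with a library left out, 4 of the 144 being those for all groups, where a replicate number was left out of every group. All 255 values of named genes with RLE, library size alone, the replicate term or DESeq2 stayed past the threshold, as did 499 of 512 with a library left out. For 1 more DESeq2 gave no adjusted p. Values of named genes were not taken with limma-voom, the other filters, the fit to only the groups compared or the fits chosen later. As the fit to only the groups compared called no gene between 21dpa and 28dpa, the 4 named genes of that pair were not called in it. The distance of 28dpa from Intact was 40.2% of that of 1dpa over a larger set of variable genes and 43.6% over all tested genes, against 39.7%. These shares include the spread among Intact libraries. Over the larger set Intact libraries lay 44.3 from each other and 1dpa lay 180.5 from them, and over all tested genes 69.8 and 249.1. Over all tested genes 12dpa lay farther out than 9dpa. The permutation p stood at its smallest value throughout and says nothing about stability. The causes of the shifts below were not tested unless named.

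Asking for a log2 fold change of at least 1, a stricter rule, left 7902, 5286, 3638, 2623, 3650, 2736, 2163 and 1704 genes against Intact from 1dpa to 28dpa in order, 3846, 1689, 837, 1216, 1058, 497 and 31 between neighbouring time points in order, and 7484 between 1dpa and 28dpa. With only the groups compared in the fit, which leaves fewer samples to estimate the spread, 1279 genes were called between 15dpa and 21dpa and 0 of 16380 between 21dpa and 28dpa. limma-voom called 5291 between 6dpa and 9dpa, 3839 between 15dpa and 21dpa and 316 between 21dpa and 28dpa, where DESeq2 called 347.

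With 1 library left out, counts against Intact lay between 13036 and 13128 at 1dpa, 10760 and 11137 at 3dpa, 8788 and 9078 at 6dpa, 6663 and 6907 at 9dpa, 9055 and 9363 at 12dpa, 7082 and 7320 at 15dpa, 5840 and 6567 at 21dpa, and 4402 and 4833 at 28dpa. Between neighbours they lay between 9064 and 9480, 4089 and 5115, 2162 and 3222, 3982 and 4729, 3798 and 4481, 1118 and 2525, and 21 and 249, in order of time. They lay between 12732 and 12886 for 1dpa and 28dpa, and 4802 and 5819 for 12dpa against the mean of its neighbours. For all groups together 1 replicate number was left out of every group, 9 libraries at once, which gave between 15043 and 15943.

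A term for the replicate number as a block moved no count by over 1.5 times (13340 genes at 1dpa and 5154 at 28dpa against Intact, 166 between 21dpa and 28dpa). The counts gave no sign that equal numbers pair the libraries, though the labels leave this open. The deviations of 144 same-numbered pairs from their group means had a mean correlation of 0.0012 (-0.213 to 0.292), against -0.000298 for pairs of other numbers. Of the same-numbered pairs 25 were over 0.1, and 6 of 36 libraries correlated best with their own number.

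Medians of the change left at later times moved by more than the spread between libraries as follows. With genes chosen on replicates 3 and 4 and measured on 1 and 2, the lower genes were at -1.07 at 3dpa and -0.57 at 6dpa, and the higher genes at 1.09 at 1dpa and 0.29, 0.43, 0.27 and 0.15 from 9dpa to 21dpa. The set at least 8-fold lower was then at -3.83, -3.27, -2.33, -1.47, -1.40 and -1.15 from 1dpa to 15dpa and -0.70 at 28dpa, and the set at least 8-fold higher at 3.77 at 1dpa, 0.57 at 21dpa and 0.93 at 28dpa. With RLE scaling the lower genes were at -1.02 at 3dpa, the higher genes at 0.58 at 3dpa, 0.38 at 6dpa and 0.45 at 12dpa, and the set at least 8-fold lower at -2.91 at 3dpa and -2.11 at 6dpa. Asking for a log2 fold change of at least 1, which keeps genes of larger change, gave -2.17, -1.27, -0.63, -0.43 and -0.67 from 1dpa to 12dpa for the lower genes, and 1.80, 0.97, 0.61, 0.57, 0.75, 0.52, 0.48 and 0.28 from 1dpa to 28dpa for the higher genes. Depth limits genes of few counts: 197 of the 1337 genes at least 8-fold lower had under 3 counts at 1dpa over both libraries.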

Other observations

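The groups by level at 6dpa, the highest groups, and the tests on neighbouring genes were chosen only after the main results had been seen; the counts of other splits of the libraries were planned, but how they would be read was written down only after the counts of genes had been seen.

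The genes that fell 8-fold or more at 1dpa differed in how far they had come back by 6dpa. They were parted by their level at 6dpa on replicates 1 and 2 and measured on replicates 3 and 4; the sets follow from where the range was parted and do not show that there are separate stages. An early set of 290 genes, at 50% of Intact or more at 6dpa, had medians of 11.2% of Intact at 1dpa, 34.8% at 3dpa and 98.5% at 6dpa, and lay between 80.5% and 94.9% from 9dpa to 28dpa. A late set of 498 genes, at least 8-fold lower at 6dpa, was at 4.29% at 1dpa, 4.54% at 3dpa and 6.42% at 6dpa, and then at 12.7% at 9dpa, 27.8% at 12dpa, 23.1% at 15dpa, 33.6% at 21dpa and 45.7% at 28dpa. It was lower at 15dpa than at 12dpa, without overlap of the 2 single libraries of each group (22.8% to 23.5% against 26.6% to 26.9%). The 549 genes between them stood at 31.3% at 6dpa and 76.1% at 28dpa. The early set did not rise steadily after 6dpa, with 91.0% at 9dpa, 80.5% at 12dpa, 94.9% at 15dpa and 82.2% at 21dpa. Its single libraries overlapped between 12dpa (72.8% to 85.1%) and 15dpa (83.8% to 99.1%), but not between 9dpa (90.03% to 90.25%) and 12dpa. No test was made of these medians. With 2 libraries against 2 a lack of overlap can easily come by chance, and the sets were not measured with the replicates exchanged.

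Genes were also sorted by the group in which they were highest. Over 12418 genes, on replicates 1 and 2, the highest group was 1dpa for 3968 genes and Intact for 2795. It was 3dpa for 1433, 21dpa for 1287, 6dpa for 840, 28dpa for 823, 15dpa for 555, 12dpa for 424 and 9dpa for 293. On replicates 3 and 4 the same group was highest for 92.9% of the 1dpa genes, 77.6% of the Intact genes and 65.5% of the 6dpa genes, but for 26.4% of the 21dpa genes and 18.4% of the 9dpa genes. Over all genes 69.5% had the same highest group, against 18.5% expected from the sizes of the classes.

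Genes that fell 8-fold or more at 1dpa were neighbours in the assembly ASM307304v1 more often than other tested genes of similar level. Neighbours here are tested genes that follow each other in order of position, at any distance. Genes that were not tested can lie between them, also in the runs given below. The 1290 genes formed 304 neighbouring pairs where 112.8 were expected, and none of 10000 permutations within 20 bins of expression gave more than 149 (ratio 2.70, p = 1e-04, the smallest they can give), which argues against similar levels of neighbours as the cause. Without pairs whose annotated spans overlap the ratio was 2.66 (269 pairs, 101.2 expected), which argues against reads shared by overlapping genes. The 680 genes that rose 8-fold or more formed 155 pairs where 29.2 were expected. Reads shared between near-identical copies, such as neighbouring duplicates, were not tested, as no sequence was used here. They remain open beside a shared control of neighbours and, for the genes that fell, a shared loss with removed tissue.

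There were 25 runs of 4 or more such neighbours among the genes that fell and 7 among those that rose; those given here were chosen after their values had been seen. The longest, 11 genes from LOC112554526 to LOC112553826, had a median of 10.4 CPM in Intact, 0.850 at 1dpa, 5.92 at 9dpa, 3.36 at 12dpa, 7.54 at 15dpa and 9.78 at 28dpa. The 6 genes from LOC112561576 to LOC112571500 took another course at 12dpa, with 167.0 CPM in Intact, 0.577 at 1dpa, 3.28 at 9dpa, 28.8 at 12dpa, 19.9 at 15dpa and 52.6 at 28dpa. The longest run that rose, 8 genes from LOC112560101 to LOC112560674, went from 1.06 CPM in Intact to 21.8 at 1dpa, 7.16 at 3dpa and 1.54 at 28dpa.

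Other splits of the libraries were counted in fits to the groups compared. Against Intact the real split was the 1 of 35 with as many genes at every time point, the smallest share that 35 splits can give. These shares were not adjusted for the number of comparisons. The other splits mix the groups compared, so a difference between groups widens their spread and lowers their counts. The splits therefore argue against chance only as far as that smallest share. The real split gave 12530 genes at 1dpa, 10549 at 3dpa, 9310 at 6dpa, 7240 at 9dpa, 9300 at 12dpa, 7524 at 15dpa, 6369 at 21dpa and 4588 at 28dpa, and the highest of the others was 3 or less. It was also the 1 of 35 with as many genes between 1dpa and 3dpa (8282, highest other 0), 3dpa and 6dpa (4628, 223), 6dpa and 9dpa (3154, 285), 9dpa and 12dpa (4368, 242), 12dpa and 15dpa (3922, 3), 15dpa and 21dpa (1279, 282) and 1dpa and 28dpa (11817, 0). For the 9 groups together it was the 1 of 100 (16102, 2480). Between 21dpa and 28dpa the splits say nothing about chance, since the real split called 0 genes in this fit and each of the 35 of 35 splits had to give as many; the highest of the others was 113.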
